A study of Homo sapiens with 8 samples.

How the data were processed

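RNA of HSC39 cells was measured on 8 Affymetrix whole-transcript arrays, with the Human Gene 1.0 ST platform table. Per the labels' protocols, cells grown in RPMI with 10% fetal calf serum were transfected with siRNA, RNA was extracted with a column kit, and biotin-labelled sense cDNA was hybridised. The protocol text names only TRIM44 siRNA, also for the samples labelled negative siRNA, and the series text speaks of untreated cells; the sample labels were used. The deposited values are log2 expression levels, 1 per probe set and array, for 32321 probe sets, and per the submitters' processing notes limma was used. Sorted values differed by at most 0.180 between arrays at the same rank, so the authors had brought the deposited log2 values close to a common distribution; the method, the genome build and any filter are not given in the sources used here. Signal over background is not given either, so dim probe sets could not be told from absent ones.

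Gene names came from the probe annotation of the series, looked up by gene ID in a RefSeq table of assembly GRCh38.p14 (19128 found, 0 symbols changed). The 19158 probe sets with exactly 1 symbol, of 18404 genes, were tested, with no filter on level; 1388 with several symbols were left out, and 11775 with none are given only in the closing section. For 637 genes with more than 1 probe set, each was tested and the probe set of highest mean stood for the gene where it is named. No coordinates are used, and Y-linked genes and XIST are left out.

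Groups followed the labels: 4 arrays of negative siRNA and 4 of TRIM44 siRNA, the latter 2 of siRNA 7 and 2 of siRNA 9. TRIM44 siRNA was compared with negative siRNA in a 2-group limma fit, since the series design counts 4 replicates per condition. Each reagent was compared with negative siRNA, and the reagents with each other, in a limma fit of 3 group means. Moderated t tests were 2-sided, with Benjamini-Hochberg adjustment over the 19158 probe sets and a threshold of 0.05. For TRIM44 an exact permutation test over 70 assignments was added. Differences are on the log2 scale, with the standard error (SE) of the fit. Gene lists, 30 in all with 680 of 741 listed genes measured, were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists; members were also adjusted over the list alone. Calls shared by the reagents were set beside unchanged groups simulated 50 times against the same negative arrays and beside negative arrays split 2 and 2.

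The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from those named as later choices. The rule took TRIM44; 12 genes each way for TRIM44 siRNA by size past the threshold with no overlap between groups, filled up by smallest unadjusted p; 6 each way for each reagent and for their difference by size past the threshold; and up to 4 members per list by smallest unadjusted p in the 2-group fit. Alternatives were quantile normalization, median centring, the upper 50% of probe sets by mean level, all probe sets, a trended and robust variance prior, array weights, the replicate number as a block, 3 group means, only the arrays compared, split negative arrays, an estimated correlation in camera, and leaving out each array in turn.

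The fits were tested on simulated data with 200 of 19158 probe sets changed and spreads as within the 3 groups, 10 times. Simulated probe sets varied independently, and in the 2-group fit both reagents were given the same shift. The shares recovered therefore do not say how many changed genes the fit finds in the measured data. There, TRIM44 at -0.81 only just passed (limma adjusted p = 0.0449). At a log2 size of 0.8 the 2-group fit recovered 99.2% of changed probe sets, the siRNA 7 contrast 98.6%, the siRNA 9 contrast 98.4% and their difference 96.4%. At 0.5 these shares were 90.2%, 67.8%, 66.4% and 41.2%, and 6.48%, 6.35%, 6.52% and 6.85% of calls were false. A shift of 0.2 in the mitosis list, over 18404 genes in the 2-group fit, was recovered in 100% of 20 simulations, with 0.05 other lists called on average. Genes varied independently in these simulations too. In the measured 2-group fit the estimated correlation was 0.167 for the mitosis list and 0.461 for the amino acid response list. Other splits of the measured arrays called up to 13 lists. The simulated values therefore do not give the recovery or the false calls of lists in the measured data. R 4.3.3, limma 3.58.1, statmod 1.5.0 and matplotlib 3.10.9 were used.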

Results

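Gene expression was measured in HSC39, a cell line grown from a human signet ring cell carcinoma of the stomach, after transfection with small interfering RNA (siRNA) against TRIM44 or with a negative control siRNA. TRIM44 is a tripartite motif protein that lacks the RING domain of most of its family and carries a ubiquitin-binding zinc finger. The comparison asks which transcripts differ when TRIM44 is lowered. RNA from 8 samples was hybridised to 8 whole-transcript arrays. Of these, 4 were of negative siRNA, 2 of TRIM44 siRNA 7 and 2 of TRIM44 siRNA 9, and the labels give 100 nM of TRIM44 siRNA (written nm) for 48 h. The series counts both TRIM44 reagents as 1 condition of 4 biological replicates. Nothing else states whether these were separate cultures, so the p-values measure the spread between these samples, which may be technical. Array medians lay between 6.78 and 6.87 on the log2 scale, and pairs of arrays correlated at 0.991 to 0.997 across named probe sets. On the first principal component, with 32.5% of the variance, the siRNA 9 arrays lay at 15.5 and 17.2 and negative array 2 at 13.6, while the other arrays lay between -11.8 and -5.57. The number of arrays limits the precision of every value.

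TRIM44 fell with both reagents, to 57.0% of the level with negative siRNA (95% confidence interval 49.1% to 66.1%). Its log2 level was 11.90 ± 0.11 (SD, n = 4) with negative siRNA, 11.06 ± 0.30 (SD, n = 2) with siRNA 7 and 11.12 ± 0.02 (SD, n = 2) with siRNA 9. All 4 siRNA arrays, at 10.85, 11.27, 11.10 and 11.14, lay below all 4 negative arrays, at 11.91, 12.02, 11.91 and 11.77. The log2 difference was -0.81 (SE 0.10, limma adjusted p = 0.0449 over 19158 probe sets), and a 2-sided exact permutation test of this value gave p = 0.0286, the smallest that 70 assignments allow. Against negative siRNA, TRIM44 was lower by -0.84 with siRNA 7 (adjusted p = 0.0405) and by -0.78 with siRNA 9 (adjusted p = 0.0155). The reagents differed by -0.06 (95% interval -0.36 to 0.24, adjusted p = 0.903). The size was -0.87 to -0.73 with each array left out in turn, but the adjusted p over all probe sets stayed under 0.05 only without siRNA 7 array 2 (0.0306). It reached 0.0587 without negative array 2, 0.0929 without siRNA 7 array 1, 0.103, 0.285 and 0.291 without negative arrays 4, 3 and 1, and 0.199 and 0.209 without siRNA 9 arrays 2 and 1. It was 0.108 after median centring and 0.226 with siRNA identity as a random block, an alternative chosen after seeing the data.

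**Figure D1:**
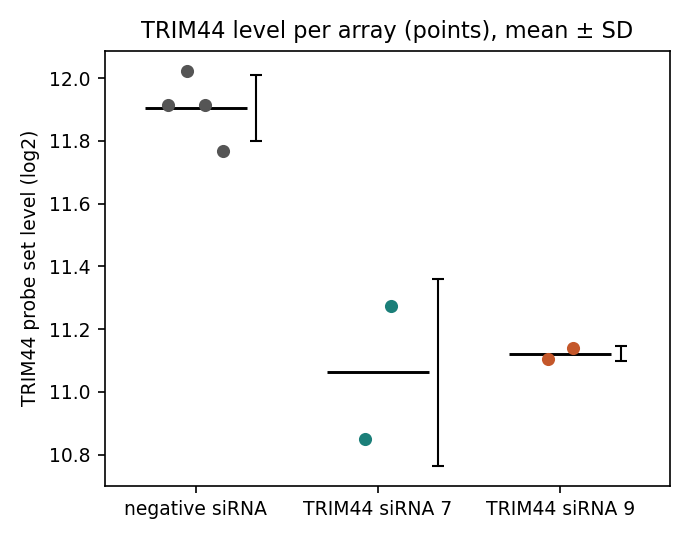
TRIM44 probe set level on the log2 scale in each of the 8 arrays (points), by siRNA, with the group mean (horizontal line) and SD (error bar, n = 4, 2 and 2). The 4 TRIM44 siRNA arrays lie between 10.85 and 11.27, below the negative siRNA arrays at 11.77 to 12.02.

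With both reagents taken as 1 condition, TRIM44 itself was the only gene past the threshold. The gene next in order was DESI2, which encodes a desumoylating isopeptidase and stood at 9.55 ± 0.11 (SD, n = 4) with negative siRNA and 10.13 ± 0.06 (SD, n = 4) with TRIM44 siRNA, a log2 difference of 0.58 (SE 0.08, adjusted p = 0.0927). At an unadjusted p under 0.05 there were 1041 probe sets of 19158, where chance gives 957.9. The 4 siRNA arrays lay above all negative arrays for 305 probe sets and below them for 242, together 2.86%, and chance gives 2.86%. The count changed with the setting. In a fit of 3 group means the genes called were TRIM44, DESI2, CYP2S1 and TAPBP. On its brightest probe set TAPBP had -0.19 with siRNA 7 and -0.99 with siRNA 9, so its call rests mainly on siRNA 9. Thus limma called 4 genes in that fit and 33 with array weights. It called 0 with the random block, after median centring and with each of negative arrays 1, 2, 3 and 4, siRNA 7 array 1 and siRNA 9 arrays 1 and 2 left out, and 2 without siRNA 7 array 2; over all settings that called 0 in limma, 592 to 1707 probe sets had an unadjusted p under 0.05.

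The genes of smallest unadjusted p whose siRNA arrays lay above all negative arrays did not pass the threshold and are given as values. Beside DESI2, log2 differences were 0.68 for SAMD5, 0.62 for UHMK1, a kinase that phosphorylates splicing factors, 0.62 for the magnesium transporter gene NIPAL1 and 0.65 for SPOPL, a cullin adaptor (adjusted p = 0.215 for the first 3 and 0.370 for SPOPL). DCUN1D3, which acts in cullin neddylation, had 0.53, and HEATR1, needed for ribosomal RNA synthesis, had 0.47. MRPL50, of the mitochondrial ribosome, had 0.45, GPR63 had 0.45, SMIM15 had 0.51, the poly(A)-binding protein gene PABPC4 had 0.35 and RAB11FIP2, of the recycling endosome, had 0.40. Beside TRIM44, those whose siRNA arrays lay below all negative arrays were the cytochrome P450 gene CYP2S1 at -0.56, ENPP1, which makes extracellular pyrophosphate, at -0.56, and GM2A, the ganglioside activator, at -0.46. TPPP, which promotes tubulin polymerisation, had -0.51, the secreted phospholipase gene PLA2G10 had -0.57, ZFYVE21 had -0.43, the cullin adaptor KLHL12 had -0.42 and BLTP3A had -0.49. The metallothionein gene MT1H, which has close paralogs that a probe set may not separate, had -0.49, the histone chaperone gene ASF1A had -0.60 and EMB had -0.50. Adjusted p ran from 0.0927 for DESI2 to 0.542 for EMB.

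Among 30 gene lists fixed before the data were examined, Wnt target genes were higher with TRIM44 siRNA, and replication-dependent histone genes were lower, the latter mainly on the siRNA 9 arrays. All 16 measured Wnt targets had a positive difference, with a median of 0.14 (camera with a preset correlation, adjusted p = 1.57e-05, and adjusted p = 0.566 with an estimated correlation). No member passed over all genes; DKK1, a secreted Wnt antagonist, had 0.43 and passed when adjusted over the list alone. BMP4 had 0.68, LGR5, a stem cell receptor gene, had 0.48 and CCND1, or cyclin D1, had 0.26. Histone genes had a median of -0.15, with 16 of 19 members lower, among them H2AC4 at -0.44, H3C1 at -0.23, H4C2 at -0.29 and H1-5 at -0.31 (adjusted p = 1.57e-05, and adjusted p = 0.566 with an estimated correlation), and no member passed. By reagent, the histone median was -0.01 with siRNA 7 (adjusted p = 0.484) and -0.23 with siRNA 9, and the Wnt median was 0.08 with siRNA 7 and 0.19 with siRNA 9. The Wnt value of siRNA 7 rests on its array 2. With genes centred over all arrays, the list mean was -0.10 on siRNA 7 array 1, 0.16 on array 2 and -0.10 on average on the negative arrays.

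Amino acid response genes, the targets of ATF4, were lower, with a median of -0.13 and 19 of 24 members below 0, including the stress gene DDIT4 at -0.48, the glutathione-degrading enzyme gene CHAC1 at -0.66, the cystine transporter gene SLC7A11 at -0.39 and ATF4 at -0.21 (adjusted p = 0.00162, and adjusted p = 0.769 with an estimated correlation). Unfolded protein response genes were higher by a median of 0.08, with 15 of 20 above 0, including HSPA5, the main chaperone of the endoplasmic reticulum, at 0.19 and SDF2L1 at 0.24 (adjusted p = 0.0145, and 0.769 as adjusted p with an estimated correlation). ERK output genes were higher by 0.10, with 17 of 23 above 0, including PHLDA1 at 0.25 and the feedback inhibitor gene SPRY2 at 0.23 (adjusted p = 0.0332, and adjusted p = 0.566 with an estimated correlation). Ribosome biogenesis genes were higher by 0.04, with 19 of 22 above 0, including RRS1 at 0.27 and UTP20 at 0.30 (adjusted p = 0.0332, and adjusted p = 0.769 with an estimated correlation). No member of these 4 lists passed over all genes or over its list alone. For 2 of these lists negative array 2 lay above the other negative arrays. Its list mean, with genes centred over all arrays, was 0.05 for unfolded protein response genes, against -0.08 to -0.06 on the other negative arrays. It was 0.05 for ERK output genes, against -0.11 to -0.05, with the siRNA 7 arrays at 0.02 and -0.05 and the siRNA 9 arrays at 0.14 and 0.08. By reagent, medians with siRNA 7 and siRNA 9 were -0.05 and -0.22 for the amino acid response, 0.08 and 0.11 for the unfolded protein response, 0.03 and 0.12 for ERK output, and 0.13 and 0.01 for ribosome biogenesis. The amino acid list mean split within groups, at 0.28, -0.07, 0.22 and -0.10 on negative arrays 1 to 4 and 0.28 and -0.28 on the siRNA 7 arrays. Its siRNA 7 median was 0.19 without siRNA 7 array 2 (adjusted p = 0.000836) and -0.30 without siRNA 7 array 1 (adjusted p = 1.50e-06), and its median for both reagents was -0.07 without negative array 1 (adjusted p = 0.0804). Without negative array 1 the number of lists past the threshold was 2 in place of 6, the histone and Wnt lists, which passed with each array left out. The call also ended for the amino acid response without siRNA 7 array 2 (adjusted p = 0.125), for the unfolded protein response without negative array 4 (0.131) or siRNA 7 array 1 (0.1003), for ERK output without negative array 3 (0.107) or 4 (0.116), siRNA 7 array 1 (0.1003) or siRNA 9 array 1 (0.0604), and for ribosome biogenesis without negative array 4 (0.114), siRNA 7 array 1 (0.104) or siRNA 7 array 2 (median 0.03, 0.694). With the upper 50% of probe sets the ERK output and ribosome biogenesis calls ended (adjusted p = 0.221 and 0.0646), the latter also with array weights (0.521).

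The other 24 lists did not pass, with adjusted p from 0.199 to 0.976. Immune and stress lists had medians of 0.01 for the interferon response, 0.02 for NF-kappaB targets, -0.03 for p53 targets and 0.03 for oxidative stress targets of NRF2. The proliferation lists had -0.04 for DNA replication and -0.02 for mitosis, and the apoptosis regulators had 0.03. Metabolic lists had 0.03 for cholesterol synthesis, -0.02 for fatty acid synthesis, 0.07 for hypoxia and glycolysis, -0.00 for oxidative phosphorylation and -0.01 for mTOR pathway components. GPAM, an enzyme of glycerolipid synthesis, had -0.51 and passed over the fatty acid list alone. The hypoxia median was -0.12 with siRNA 7 and 0.19 with siRNA 9, and with both reagents the list passed without negative array 2 (median 0.14, adjusted p = 0.00164), with array weights (0.14, 0.00177) and without siRNA 7 array 1 (0.11, 0.00436). Ribosomal protein genes had -0.02, TGF-beta targets 0.02, autophagy and lysosome genes -0.02, and small RNA machinery 0.06. The ribosomal protein list passed without negative array 4 (median -0.05, adjusted p = 0.0160) and without siRNA 7 array 2 (-0.05, 0.0324). Cholesterol synthesis passed without negative array 2 (0.06, 0.0429), and fatty acid synthesis without siRNA 9 array 2 (-0.04, 0.0382). TRIM family genes had 0.00 and deubiquitinases -0.00, and genes neighbouring TRIM44 had 0.03. Of the cell type markers, epithelial adhesion genes had -0.05, gastric differentiation genes 0.01, intestinal differentiation genes -0.01, mesenchymal and fibroblast markers -0.00, and leukocyte and endothelial markers -0.03. For the gastric and TRIM family lists the test ranked the genes as lower while median and mean were above 0.

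Taken alone against negative siRNA, siRNA 7 changed 13 genes, of which 12 fell. CLCA1, a secreted protein of goblet cells, rose by 1.74 (SE 0.16, adjusted p = 0.00429), from 7.39 ± 0.32 (SD, n = 4) to 9.13 (n = 2). USP28, a deubiquitinase, had -0.87 and fell at the edge of the threshold (adjusted p = 0.04998), and the histone chaperone gene ASF1A fell by 0.83. MBNL3, a splicing regulator, fell by 0.82, CYP2S1 fell by 0.72 and the ubiquitin ligase gene HECTD3 fell by 0.70, with adjusted p of 0.0405 to 0.0417. The count was 4 without negative array 1, 35 without negative array 2, 1 without negative array 3 or 4, 32 without siRNA 7 array 1, 4 without siRNA 7 array 2, 1 without either siRNA 9 array. After median centring it was 1, CLCA1, which was higher, and with all probe sets tested limma called 0 (1826 at an unadjusted p under 0.05).

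By list, ribosome biogenesis genes were higher with siRNA 7 by a median of 0.13, with 20 of 22 above 0 and RRS1 at 0.37 past the threshold over the list alone. Wnt targets were higher by 0.08 and mitosis genes by 0.06. Fatty acid synthesis genes were lower by -0.08, with FADS1, a fatty acid desaturase gene, at -0.59 past the threshold over the list alone. In this order the adjusted p was 4.06e-05, 0.0195, 0.0460 and 0.0181, and with an estimated correlation the adjusted p was 0.558, 0.867, 0.867 and 0.558. Without siRNA 7 array 2 the ribosome biogenesis median was 0.06 and the call ended (adjusted p = 0.0957), and the Wnt median was 0.01 (adjusted p = 0.979). The Wnt and fatty acid calls also ended without negative array 2 (adjusted p = 0.0564 and 0.0684), the fatty acid call without siRNA 7 array 1 (0.214), and the mitosis call after median centring (0.0593), after quantile normalization (0.0738), with all probe sets (0.0762), with array weights (0.120) and with 5 of the 8 arrays left out in turn (0.0519 to 0.708). With the upper 50% of probe sets the adjusted p was 0.178 for Wnt targets, 0.178 for mitosis and 0.0563 for fatty acid synthesis. Some lists gained a call. Hypoxia and glycolysis passed without negative array 1 (-0.19, 0.000197), without negative array 3 (-0.16, 0.0399) and with the trended prior (-0.12, 0.0498). The unfolded protein response passed without negative array 2 (0.08, 0.00382), with array weights (0.08, 0.0415) and with the trended prior (0.08, 0.0428). The amino acid response passed with array weights (-0.12, 0.0234). DNA replication genes had a median of -0.05, and -0.07 without siRNA 7 array 2. Mesenchymal and fibroblast markers had -0.05, and -0.12 without siRNA 7 array 1.

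Alone against negative siRNA, siRNA 9 changed 177 probe sets of 176 genes, 64 higher and 113 lower. The chemokine gene CCL24 rose by 1.22 (SE 0.13, adjusted p = 0.00326), from 6.76 ± 0.19 (SD, n = 4) to 7.98 (n = 2). The other largest rises were the extracellular matrix gene OLFML2B by 1.16, CAMSAP2, which binds microtubule minus ends, by 1.07, the oxysterol hydroxylase gene CYP39A1 by 1.06, MAB21L3 by 1.05 and the guanine deaminase gene GDA by 0.94. TOMM22, a receptor for protein import into mitochondria, fell by 1.11 (SE 0.11, adjusted p = 0.00245), from 11.99 ± 0.08 (SD, n = 4) to 10.87 (n = 2), and its other probe set had -1.01 (adjusted p = 0.00326). UBE2N, a ubiquitin-conjugating enzyme gene, fell from 10.05 ± 0.11 (SD, n = 4) to 9.05 (n = 2). UBE2NL, at -1.01, is a near-identical copy whose signal a probe set may not separate from it. PLOD3, a collagen lysyl hydroxylase gene, fell by 0.94. TAPBP, which loads peptides onto MHC class I, fell by 0.99 on its brightest probe set, while its other probe sets had -0.18 and -0.59 and did not pass (adjusted p = 0.468 and 0.644). UBD, a ubiquitin-like modifier gene, fell by 1.80 on its brighter probe set, and its other probe set had 0.17 (adjusted p = 0.524). The count was 1067 without negative array 2, where 709 were higher and 358 lower, 2082 with array weights, where 1232 were higher and 850 lower, 74 without negative array 1, 47 without negative array 3 and 28 with all probe sets tested. It was 0 without either siRNA 9 array, when the remaining array is assumed to vary like the other groups, with 1449 and 1543 probe sets at an unadjusted p under 0.05 in limma.

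Among the lists, histone genes were lower with siRNA 9 by a median of -0.23, with 17 of 19 members below 0. H2AC4 fell by 0.72 and the linker histone gene H1-5 fell by 0.62 over all genes, and 8 members passed when adjusted over the list alone (adjusted p of the list = 1.94e-08, and adjusted p = 0.109 with an estimated correlation). Hypoxia and glycolysis genes were higher by 0.19, with 21 of 24 above 0, and 9 passed over the list alone, including the histone demethylase gene KDM3A (8.83 with negative siRNA and 9.83 with siRNA 9), the collagen prolyl hydroxylase gene P4HA1 at 0.64 and the hexokinase gene HK2 at 0.55, though none over all genes. This list had adjusted p = 5.68e-05, and adjusted p = 0.815 with an estimated correlation. List members outside the rule for named genes were chosen after their values were seen. Negative array 2 had a hypoxia list mean of 0.20, beside 0.26 and 0.22 on the siRNA 9 arrays and -0.26, -0.11 and -0.02 on the other negative arrays. Wnt targets were higher by 0.19 (adjusted p = 0.000242, and adjusted p = 0.815 with an estimated correlation), with 15 of 16 above 0 and 6 past the threshold over the list alone, including BMP4 at 0.99, DKK1 at 0.46 and CCND1 at 0.41. Amino acid response genes were lower by -0.22 (adjusted p = 0.000301, and adjusted p = 0.815 with an estimated correlation), with 5 past the threshold over the list alone, CHAC1 at -1.10, DDIT4 at -0.76, SLC7A1, TRIB3 and ATF4 at -0.40. Mitosis genes were lower by -0.03 (adjusted p = 0.0155, and adjusted p = 0.815 with an estimated correlation), with KIF20A at -0.51, PLK1 at -0.37 and KIF2C at -0.33 past the threshold over the list alone, and ribosomal protein genes were lower by -0.05 (adjusted p = 0.0365, and adjusted p = 0.815 with an estimated correlation). The mitosis call ended without negative array 2 (median -0.07, adjusted p = 0.291), without siRNA 9 array 1 (-0.07, 0.270) and with the upper 50% of probe sets (0.113). The ribosomal protein call ended after quantile normalization (adjusted p = 0.750), with array weights (0.0578), with the upper 50% of probe sets (0.136) and without negative array 1 (0.0710), negative array 2 (0.316) or siRNA 9 array 2 (0.167). Outside the called lists, 1 member of 7 lists passed over all genes: GINS1 of the replicative helicase fell by 0.81, SREBF2, the master regulator of cholesterol synthesis, fell by 0.69, GPAM fell by 0.70, S100A4 fell by 0.47 and ATG16L1, of the autophagy machinery, fell by 0.49. The desmosomal cadherin gene DSC2 rose by 0.44 and TNRC6A, a partner of Argonaute proteins, rose by 0.47. Some lists gained a call with siRNA 9. The unfolded protein response passed after quantile normalization (0.12, camera adjusted p = 0.0252) and without negative array 2 (0.11, 0.0288). ERK output passed after quantile normalization (0.11, 0.0365), with array weights (0.16, 0.0380) and without negative array 2 (0.14, 0.0171). Cholesterol synthesis passed without negative array 2 (0.17, 0.0288).

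**Figure D2:**
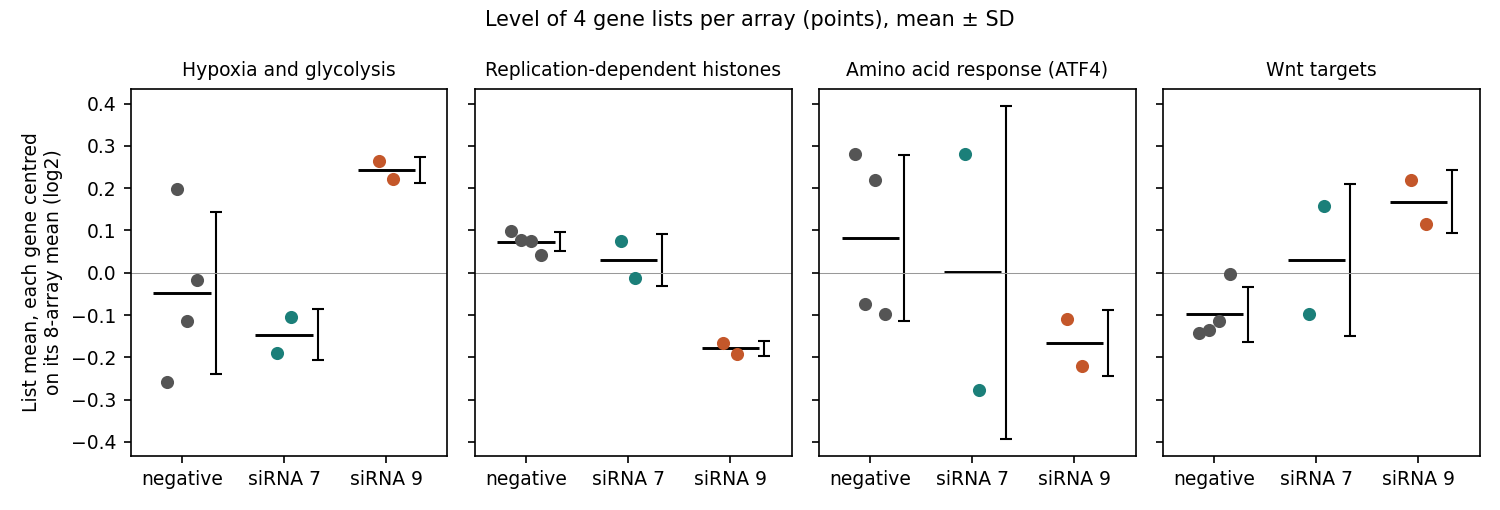
Mean log2 level of 4 gene lists in each of the 8 arrays (points) after each gene was centred on its mean over all arrays, by siRNA, with group mean (horizontal line) and SD (error bar, n = 4, 2 and 2). Histone genes lie at -0.17 and -0.19 on the siRNA 9 arrays and at 0.04 to 0.10 on the negative arrays, while negative array 2 has a hypoxia list mean of 0.20, close to the siRNA 9 arrays.

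Compared directly, siRNA 7 and siRNA 9 differed for 428 probe sets of 426 genes, 157 higher and 271 lower with siRNA 7. UBD was 2.32 higher with siRNA 7 than with siRNA 9 (on a dim probe set of mean level 5.30, and its other probe set had -0.17), CLCA1 was 1.79 higher, TOMM22 1.37, the cytochrome P450 gene CYP2B6 1.36, the atypical kinase gene MAPK6 1.29 and COQ10B, which binds coenzyme Q, 1.17. The secreted glycoprotein gene STC1 had -1.66, the fibronectin receptor subunit gene ITGA5 -1.61, USP28 -1.39, KDM3A -1.36, MAB21L3 -1.36 and CCL24 -1.24, all lower with siRNA 7. Adjusted p was 0.00248 for TOMM22 and 0.0462 for ITGA5, the smallest and largest of these 12 genes. Of the 428 probe sets, 109 had also passed for siRNA 9 against negative siRNA, 8 for siRNA 7 and 311 for neither. Of all 428, 390 had effects of opposite sign with the reagents. Choosing probe sets by their difference between the reagents favours opposite signs, so this number is no separate evidence of opposed effects. After median centring 351 passed, 181 higher and 170 lower with siRNA 7, so that the excess of lower genes did not hold, and with all probe sets tested 8 passed, 8 higher and 0 lower. The count was 1050 without negative array 2, 219 without negative array 3, 194 without siRNA 7 array 1, 47 without siRNA 7 array 2 and 0 without either siRNA 9 array (1931 and 2003 at an unadjusted p under 0.05 in limma).

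Hypoxia and glycolysis genes were lower with siRNA 7 than with siRNA 9 by a median of -0.36, with 20 of 24 below 0. KDM3A and EGLN1, an oxygen-sensing prolyl hydroxylase gene at -0.75, passed over all genes, and 13 members passed over the list alone (adjusted p of the list = 1.52e-05, and adjusted p = 0.853 with an estimated correlation). Histone genes were higher with siRNA 7 by 0.18, with 15 of 19 above 0 and H1-5 at 0.62 and H2AC4 at 0.54 past the threshold over all genes (adjusted p = 4.38e-05, and adjusted p = 0.345 with an estimated correlation). Mitosis genes were higher by 0.12, with KIF20A at 0.72, the kinase gene PLK1 at 0.64 and KIF2C at 0.50 past the threshold over all genes and AURKA and CCNB1 also past it over the list alone (adjusted p = 0.000720, and adjusted p = 0.843 with an estimated correlation). Ribosome biogenesis genes were higher by 0.13, amino acid response genes by 0.26 and ribosomal protein genes by 0.07, with no member past the threshold (adjusted p = 0.00216, 0.0320 and 0.0355; with an estimated correlation the adjusted p was 0.843, 0.920 and 0.920). After quantile normalization these 3 lists had adjusted p of 0.0577, 0.131 and 0.513, and the amino acid median was -0.08 without siRNA 7 array 1 (adjusted p = 0.735). Without siRNA 7 array 2 the ribosome biogenesis median was 0.06 (adjusted p = 0.191) and the ribosomal protein median 0.03 (adjusted p = 0.363), and without siRNA 9 array 2 the amino acid and ribosomal protein calls ended (adjusted p = 0.128 for both). These 2 calls also ended with the upper 50% of probe sets (adjusted p = 0.122 and 0.178) and with all probe sets (0.0689 and 0.0546). Wnt targets and cholesterol synthesis genes did not pass, each with a median of -0.13. Without siRNA 7 array 2 their medians were -0.21 and -0.23. DICER1, which processes small RNAs, was lower with siRNA 7 than with siRNA 9 by -0.55 (adjusted p = 0.0400), and GINS1 at 0.77, SREBF2 at 0.70 and ATG16L1 at 0.59 were higher with siRNA 7.

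TRIM44 was the only gene that passed with each reagent in the same direction, and 0 genes passed in opposite directions. Independent lists of 13 and 177 calls would share 0.0708 lower and 0.00334 higher genes, and unchanged groups simulated against the same negative arrays shared 0.02 on average over 50 simulations. When the negative arrays were split 2 and 2 between the reagents, the number shared was 1 in 1 of the 6 splits and 0 in the others, and it was 8 without negative array 2 and 0 without negative array 1, 3 or 4, siRNA 7 array 1 or either siRNA 9 array. Across the 19158 probe sets, which are not independent replicates, the effects of siRNA 7 and siRNA 9 correlated at 0.0705, against 0.334 (range 0.318 to 0.348) for unchanged groups that share the negative arrays, and at -0.123 on average (-0.268 to 0.0271) with the negative arrays split. Their covariance was 0.00183 against 0.00464 simulated, a difference of -0.00281. The effects had the same sign for 53.1% of probe sets, against 60.8% simulated. The simulated probe sets varied independently of each other, whereas those of the arrays vary together. The simulated values and their narrow ranges therefore do not show whether the observed values depart from unchanged groups.

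**Figure D3:**
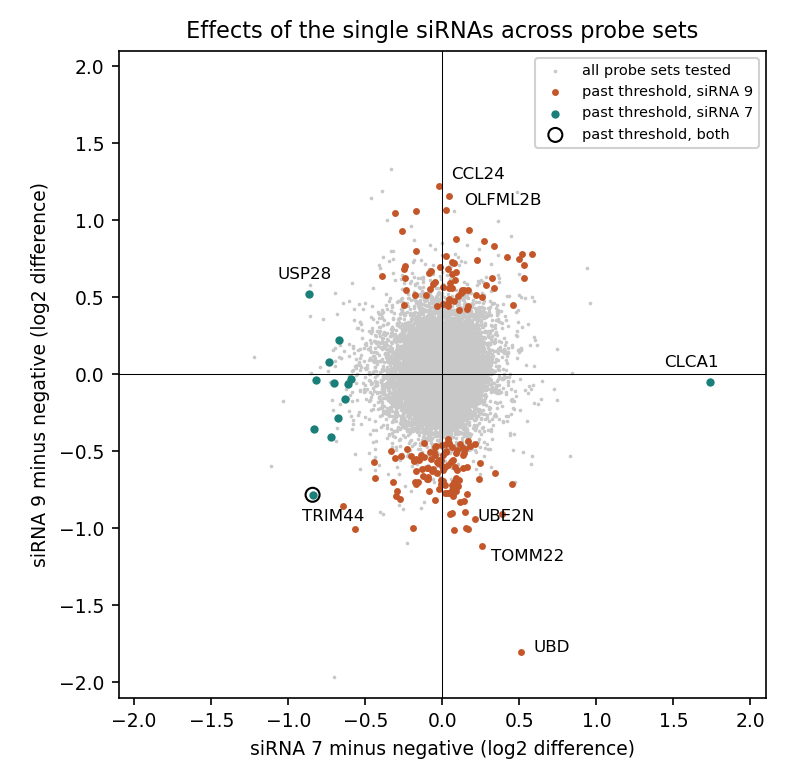
Log2 difference from negative siRNA for siRNA 7 (horizontal axis) and siRNA 9 (vertical axis), 1 point per probe set for the 19158 tested (grey), with probe sets past the threshold for siRNA 7 (teal), siRNA 9 (orange) and both (black ring). TRIM44 at -0.84 and -0.78 is the only probe set past the threshold with both reagents.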

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

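Tests of unequal knockdown and of an axis shared with negative array 2 were chosen only after the difference between the reagents was seen; the other tests were set before their results. The effects of siRNA 7 and siRNA 9 differed by a direct test for 428 probe sets. Per gene, siRNA 7 minus siRNA 9 was 2.32 for UBD, 1.79 for CLCA1, 1.37 for TOMM22, 1.36 for CYP2B6, 1.29 for MAPK6, 1.17 for COQ10B, 1.15 for UBE2N, 1.15 for PLOD3, 1.09 for UBE2NL and 0.80 for TAPBP. It was 0.77 for GINS1, 0.70 for SREBF2, 0.62 for H1-5, 0.59 for ATG16L1 and 0.54 for H2AC4. The UBD probe set was dim (mean level 5.30), and the other UBD probe set had -0.17 (limma adjusted p = 0.562). Other probe sets of TAPBP had 0.36 and -0.52 (limma adjusted p = 0.141 and 0.710). Negative differences were -1.66 for STC1, -1.61 for ITGA5, -1.39 for USP28, -1.36 for KDM3A, -1.36 for MAB21L3, -1.24 for CCL24, -1.23 for CYP39A1, -1.12 for OLFML2B, -1.04 for CAMSAP2, -0.79 for MBNL3, -0.64 for HECTD3 and -0.55 for DICER1.

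The siRNA 9 arrays against the other 6 gave 306 genes, the most of all 28 pairs of arrays, and the next pair, siRNA 7, gave 13. This ranking cannot tell an effect of the reagent from 2 arrays that are alike for technical reasons, since separate cultures are not stated. A TRIM44 RNA level lower with siRNA 9 by at least 0.5 is argued against, since the upper 95% limit of the difference was 0.24. The size of 0.5 was set after the difference between the reagents was seen. A smaller difference in RNA stays open, as does one in TRIM44 protein, which the arrays do not measure. An array axis shared with negative array 2 cannot be told apart from an effect of the reagents: over the 428 probe sets the deviation of that array from the other negative arrays correlated at -0.468 with siRNA 7 minus siRNA 9, short of the -0.5 set for the test. In negative array 2, 71.0% of these probe sets deviated towards siRNA 9. A sequence-specific effect of a reagent on transcripts other than TRIM44 also stays open and was not tested, since the siRNA sequences are not given in the sources used here.

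With the preset correlation, list medians differed between the reagents as well: siRNA 7 minus siRNA 9 was -0.36 for hypoxia and glycolysis, 0.26 for the amino acid response, 0.18 for histones, 0.13 for ribosome biogenesis, 0.12 for mitosis and 0.0718 for ribosomal proteins. None of these 6 lists passed with an estimated correlation (camera adjusted p 0.345 to 0.920). The amino acid median was -0.08 without siRNA 7 array 1. For hypoxia and glycolysis genes, the mean level ranged over 0.46 among the 4 negative arrays, 1.18 times the size of the difference in means between the reagents (-0.39), so samples with the same siRNA lay as far apart as the reagents did. This rests on negative arrays 1 and 2: the ratio was 0.804 without array 1 and 0.619 without array 2, so drift stays open as an explanation. For histone genes that range was 0.06, only 0.269 times the difference of 0.21. This argues against drift of the size seen among the negative arrays as the whole cause. The siRNA 7 arrays lay at 0.07 and -0.01 and the siRNA 9 arrays at -0.17 and -0.19. The range of the negative arrays cannot exclude a technical difference carried by both siRNA 9 arrays. Whether TRIM44, the reagent or such a technical difference sets the histone level was not tested. The histone call was lost with an estimated correlation (camera adjusted p = 0.345).

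Some samples lay far from the other 3 of the negative group. These were negative array 1 for MT1H (9.65, others 9.27 on average) and VIL1 (11.95, others 12.04), negative array 2 for MAB21L3 (6.08, others 5.39), DNAJC3 (9.38, others 9.12) and SPRY2 (8.68, others 8.43), and negative array 4 for PABPC4 (10.68, others 10.59), CDH1 (11.93, others 12.05) and RAN (10.70, others 10.76). The mean level of the intestinal differentiation list on negative array 2 was 0.13, against -0.02 on the others. Chance marks about 1 in 20 groups, which gives 8.05 of the 161 genes examined, where 8 were seen, and 1.5 of 30 lists, where 1 was seen.

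Among the 11775 probe sets without a listed gene, which the comparisons did not use, 4 passed the threshold for siRNA 9 against negative siRNA, 1 higher and 3 lower, and 0 passed in the other limma contrasts. At an unadjusted p under 0.05 there were 1268 for siRNA 9, 552 for siRNA 7, 537 for both reagents and 1383 for their difference, where chance gives 588.75.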

How the results depend on the processing

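The tests with a random block for siRNA identity, and with an estimated correlation for the lists of the single reagents and their difference, were chosen only after the data were seen; the other alternatives were planned, for the lists as alternatives of the list test as a whole. TRIM44 was lower in all 16 alternatives, by -0.88 to -0.73, but stayed past the threshold in 6 of them (adjusted p 0.00274 to 0.998). Arrays give no depth, and signal over background is not given in the sources used here. Of the values for single genes, 3008 kept their side of the threshold and direction, 166 lost the call, 27 gained it, 12 without a call changed sign and 0 with a call reversed.

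For both reagents, 1 gene became 4 with 3 group means, 2 with the upper 50% of probe sets, 2 with the trended prior, 33 with array weights, and 0 with all probe sets, with median centring (TRIM44 -0.81, adjusted p = 0.108) and with the random block (TRIM44 -0.81, adjusted p = 0.226; correlation between arrays of 1 reagent 0.345). For siRNA 7, 13 genes became 64, 83 and 70 with the upper 50%, the trended prior and array weights, 1 with median centring, 1 with its own arrays only and 0 with all probe sets. For siRNA 9, 177 became 390, 405, 2082 and 28 with the upper 50%, the trended prior, array weights and all probe sets. For the difference, 428 became 703, 792, 1063 and 8 (8 higher, 0 lower), and 807 with the arrays of the reagents only. The 1 gene shared by the reagents became 5, 7, 9 and 0, 0 with median centring, and 0 in 5 of the 6 splits of the negative arrays (1 in the other). Where a count was 0, limma gave 592 to 1707 probe sets for both reagents and 1665 to 1826 for siRNA 7 at an unadjusted p under 0.05. The cause of these changes was not tested.

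With an estimated correlation 0 lists passed for both reagents (6 in the main analysis), 0 for siRNA 7 (4), 0 for siRNA 9 (6) and 0 for their difference (6), with smallest adjusted p of 0.566, 0.558, 0.109 and 0.345 in camera of limma. Lists for siRNA 7 fell to 1 with the upper 50% of probe sets, and lists for the difference to 3 with quantile normalization.

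Leaving out each array in turn gave 0 to 2 genes for both reagents with TRIM44 at -0.87 to -0.73, 1 to 35 for siRNA 7, 0 to 1067 for siRNA 9, 0 to 1050 for the difference and 0 to 8 shared. Lists were 2 to 8, 3 to 5, 5 to 7 and 4 to 7 for both reagents, siRNA 7, siRNA 9 and the difference. Where this leaves 1 array of a reagent, that array is assumed to vary like the other groups. The amino acid response reversed: its median for siRNA 7 against negative siRNA was 0.19 without siRNA 7 array 2 (adjusted p = 0.000836) and -0.30 without siRNA 7 array 1, and siRNA 7 minus siRNA 9 was -0.0774 without siRNA 7 array 1 (adjusted p = 0.735) and 0.41 without siRNA 7 array 2. The test for Wnt targets with siRNA 7 turned without siRNA 7 array 2, with a median of 0.0128 (adjusted p = 0.979), against 0.14 without siRNA 7 array 1. The cause was not tested.

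The 3 groups share replicate numbers 1 and 2, and the sources used here do not state whether these numbers pair the samples. Deviations of same-numbered arrays correlated at 0.268 and 0.306 between negative siRNA and siRNA 7. They correlated at 0.0583 and 0.131 between negative siRNA and siRNA 9, and at 0.0244 between the reagents. A pairing or batch behind the numbers therefore stays open. A replicate block drops negative arrays 3 and 4 from the comparisons with negative siRNA, since replicate numbers 3 and 4 occur only there. Those comparisons then rest on negative arrays 1 and 2 and do not show an effect of pairing alone. With the replicate block the counts were 0 for both reagents (TRIM44 -0.88, adjusted p = 0.998), 0 for siRNA 7, 44 for siRNA 9, 450 for the difference and 0 shared (limma, 733 and 1665 at an unadjusted p under 0.05 for both reagents and siRNA 7). With that block 6 lists passed for both reagents, but 1 higher and 5 lower in place of 4 and 2. The unfolded protein response (adjusted p = 0.409), ERK output (0.474) and ribosome biogenesis (0.0942) no longer passed, while ribosomal proteins (-0.07, 0.00147), epithelial adhesion (-0.05, 0.0160) and intestinal differentiation (-0.06, 0.0497) did. For siRNA 7 the mitosis list no longer passed (0.603), while hypoxia and glycolysis (-0.13, 0.0399) and epithelial adhesion (-0.07, 0.0379) did.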

Other observations

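The split tests in this part were set before their results, and no test here was chosen only after the result was seen. The list of small RNA machinery, which siRNAs themselves use, did not differ past the threshold between the reagents (camera adjusted p = 0.192). Its median for siRNA 7 minus siRNA 9 was -0.11, and -0.14 without siRNA 7 array 2. Of its 15 members 2 did differ past the threshold, DICER1 at -0.55 and AGO3 at -0.59 for siRNA 7 minus siRNA 9. Against negative siRNA, TNRC6A rose by 0.47 with siRNA 9 (adjusted p = 0.0333), and it, AGO3 and TNRC6C were the 3 members past the threshold over the list alone. DICER1 had -0.58 with siRNA 7 (adjusted p = 0.0783) and passed over the list alone. AGO3, TNRC6C and the p53 targets named next were chosen after their values were seen. Among p53 targets, CDKN1A and RRM2B passed over the list alone with siRNA 7, in opposite directions, and TNFRSF10B, a death receptor gene, with siRNA 9.

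Of 35 splits of the 8 arrays into 4 and 4, 3 gave at least the 1 gene of the real split, so chance could not be excluded for that count. The highest other split gave 58, with negative array 2, siRNA 7 array 2 and both siRNA 9 arrays on the same side. At several times the real count, this points to a structure of the samples other than TRIM44 siRNA against negative siRNA. The siRNA 9 arrays alone gave 306 genes against the other 6, so a part from siRNA 9 cannot be told apart. What that structure is was not tested, and on the first principal component siRNA 7 array 2 (-5.70) lay apart from the other 3 arrays on its side of the split. On the second component, with 23.3% of the variance, it lay at 16.7, near negative array 2 at 14.8. The siRNA 9 arrays lay there at -12.0 and -5.88. Negative array 2 and siRNA 7 array 2 together gave 5 genes against the other 6 arrays. As many lists as the real 6 were shifted in 12 splits, with 13 as the highest other. Chance could not be excluded for any list by its median: medians at least as large in size came from 4 splits for Wnt targets (0.14, highest other 0.19), 2 for histones (0.15 in size, highest other 0.17) and 14 for the amino acid response (0.13 in size, highest other 0.30). They came from 3 splits for the unfolded protein response (0.08, highest other 0.12), 2 for ERK output (0.10, highest other 0.17) and 16 for ribosome biogenesis (0.04, highest other 0.08).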
